A study of Drosophila melanogaster with 6 samples.

How the data were processed

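RNA from whole *Drosophila melanogaster* embryos, collected and aged at 25 °C to 16-20 h, was compared between animals carrying the allele pair *ft fd5-5/ftX13*, which the series describes as null for *fat* (here *ft* null, n = 4 libraries), and *w^1118* (n = 2 libraries). The *w^1118* strain carries a deletion in the eye colour gene *white* and served as the wild type. Per the labels' protocols, 10 ng of total RNA with an integrity score above 8.0 entered the SMARTer Ultra Low RNA kit, the cDNA was sheared by sonication, fragments were amplified for 12-15 cycles, and 150-base paired-end reads were taken on a NovaSeq X Plus. That kit does not mark strand, so reads from overlapping or antisense genes cannot be told apart, and PCR copies were not marked by molecular identifiers.

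The authors deposited 1 table of estimated counts per gene and library, not normalized. Per the submitters' processing notes, FastQC 0.10, Trimmomatic 0.33, Salmon 1.80 and edgeR were used with genome build dm6; the annotation release and the options are not given in the sources used here. The table held 17208 genes, of which 1726 were at 0 in all 6 libraries. Between 29.65% and 36.12% of the values in a library were not whole numbers, which is what a quantifier that shares reads among transcripts produces, and the deposited estimated counts were rounded to whole numbers before the count tests. Gene coordinates were taken from Ensembl release 115 for BDGP6.54, which uses dm6 coordinates and held 17083 of the genes; the other 125 have no position here. A Salmon estimate splits reads of near-identical genes by a model, so values of close paralogs carry more uncertainty than their counts show.

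Genes were kept by edgeR's filterByExpr, scaled by TMM factors and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) in a fit with genotype as the one term over all 6 libraries. P-values were adjusted by Benjamini and Hochberg over 11542 genes and called under 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are counts scaled to the effective library size (CPM) with TMM factors, as mean ± SD over libraries, and log2 CPM uses a prior count of 2. The common biological coefficient of variation was 18.2%. Where a genotype held 0 reads over its libraries, the fold is a lower bound against 3 counts over that genotype; with 1 to 3 reads, it is a ratio with a 95% exact Poisson interval. Bounds and intervals cover counting error only. The labels do not say whether libraries came from separate collections of embryos, so p-values measure the spread between these samples, which may be technical, and with 2 *w^1118* libraries that spread comes mostly from *ft* null.

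The design, the rule for naming genes, 33 gene lists and the alternatives below, save 1, were fixed before the data were examined. Named genes are *ft* and *w*, then, among called genes whose 4 *ft* null values all lie on 1 side of both *w^1118* values and whose average log2 CPM is at least 1, the 10 largest increases and the 10 largest decreases, and from each list up to 2 called members with the smallest p, or else the member with the highest level. Genes named outside that rule are said to be. The lists are the Fat-Dachsous pathway, core planar polarity, Hippo pathway components, Yorkie targets, Wingless targets, Notch targets, targets of EGFR, Hedgehog and Dpp, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytosolic and mitochondrial ribosomal proteins, the proteasome, cell cycle and DNA replication, cuticle proteins, chitin and apical matrix, epidermal barrier and wound genes, JNK with apoptosis and stress, heat shock genes, antimicrobial and immune genes, detoxification, the ecdysone pathway, sex determination with dosage compensation, and markers of neurons, glia, somatic muscle, visceral muscle with heart, trachea, fat body, hemocytes, midgut, Malpighian tubule with hindgut, salivary gland, and germline with maternal transcripts. Of their symbols, 927 entries matched the table and 13 did not. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, adjusted over the 33 lists, and with a correlation estimated per list and with fry as alternatives. Called genes were counted per chromosome arm and within 2 Mb of *ft* with two-sided Fisher's exact tests, adjusted over 9 regions.

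The tests were tried on simulated counts drawn from the means, dispersions and depths of these libraries, with 200 genes changed 2-fold or 4-fold and 40 more moved together by 0.5 on the log2 scale, for the same comparison of 4 against 2 libraries and 11374 genes. There, edgeR recovered 70% of 2-fold and 97% of 4-fold changes with 8.74% false calls, limma voom 68% and 96% with 7.34%, and DESeq2 (1.42.0) 81% and 97% with 21.6%. Camera called the list of 40 genes (adjusted p = 1.01e-19) and 0 of the 33 other lists. The draws used no correlation between genes, so this trial cannot show how often camera calls unchanged lists of correlated genes. In the real libraries, the estimated correlation of the lists called with the preset ran from 0.253 (cuticle proteins) to 0.797 (mitochondrial ribosomal proteins). Alternatives were DESeq2 size factors, upper quartile factors and library totals, no filter, a filter of CPM of at least 1 in 2 libraries, DESeq2, limma voom, the replicate number as a block, replicates 1 and 2 only, leaving out each library in turn, counts not rounded, and a 2-fold minimum. A further alternative, without *ft* null replicate 1 and *w^1118* replicate 2, was added after seeing the data. The first stood apart from the other mutants, whereas with 2 controls neither can be called typical. Without a *w^1118* library the remaining one is assumed to vary like *ft* null. Closing tests, shuffles and figures used Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9. All value columns of the table were used.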

Results

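Gene expression was measured in 4 libraries from *ft* null embryos and 2 libraries from *w^1118* embryos at 16-20 h of development, when cuticle is laid down and muscles and nervous system mature. *ft* encodes Fat, a giant atypical cadherin that acts in planar cell polarity and upstream of the Hippo growth pathway. Totals were 21261928, 22575469, 23421306 and 29151981 estimated counts in *ft* null replicates 1 to 4, and 29131506 and 22217098 in *w^1118* replicates 1 and 2. The comparison asks which transcripts differ between *ft* null and *w^1118* embryos, with *w^1118* as the reference. Fat protein was not measured in these data. Strain and genotype vary together here. For every gene and list below, strain background cannot be told apart from an effect of the *ft* alleles. The labels give the same 16-20 h window for every library and no mean age within it. A difference in developmental stage between the genotypes was therefore not tested, and it too cannot be told apart from an effect of the *ft* alleles. Libraries of 1 genotype correlated at a Spearman rho of 0.978 to 0.994 across genes, and libraries of different genotypes at 0.965 to 0.983; genes are not independent replicates. The first principal component, with 52.1% of the variance, separated the genotypes, and the second, with 22.3%, set *ft* null replicate 1 at 37.1 against -28.9 to -10.3 for the other *ft* null libraries.

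*ft* itself (FBgn0001075, dm6 2L from 4198404 to 4221796, minus strand) was still transcribed in the mutants at a reduced level. It stood at 30.1 ± 1.63 CPM in *ft* null (SD, n = 4) and 44.8 ± 2.17 CPM in *w^1118* (SD, n = 2), a log2 fold change of -0.57 (SE 0.106, edgeR adjusted p = 0.0249), and all 4 mutant libraries lay below both controls. With that separation the direction had to hold without each library in turn (-0.62 to -0.52). The call held only without *ft* null replicate 1 and was lost without any other single library. Whether the alleles change the transcript outside the counted part was not analysed here. The eye colour gene *w*, deleted in part in *w^1118*, was at 24, 25, 11 and 11 reads in the *ft* null libraries and at 3 and 0 reads in *w^1118*, a ratio of 13.7 (95% exact Poisson interval 4.69 to 66.4) that did not pass the threshold (log2 fold change 3.66, SE 0.91, edgeR adjusted p = 0.0671). It passed without *ft* null replicate 4 (3.90, edgeR adjusted p = 0.0493), without the filter on low counts (adjusted p = 0.0494), with replicates 1 and 2 only (4.22, adjusted p = 0.032) and in DESeq2 (adjusted p = 0.0121). Its fitted value moved to 7.18 without *w^1118* replicate 1, which held all its control reads, and to 2.92 without *w^1118* replicate 2.

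Across the transcriptome, 496 of 11542 tested genes differed, 248 higher and 248 lower in *ft* null embryos. Of these, 170 of the higher and 168 of the lower genes changed at least 2-fold. All 496 had their 4 mutant values on 1 side of both controls; among all tested genes 31.5% were separated in this way, against 13.3% by chance. Leaving out *ft* null replicate 1 raised the counts to 425 higher and 381 lower. They were lower without *ft* null replicate 2 (120 and 111), *ft* null replicate 3 (123 and 109), *w^1118* replicate 1 (133 and 72) or *w^1118* replicate 2 (101 and 72). A fit without both *ft* null replicate 1 and *w^1118* replicate 2 leaves 1 control, and its values are given with the alternatives below.

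**Figure D1:**
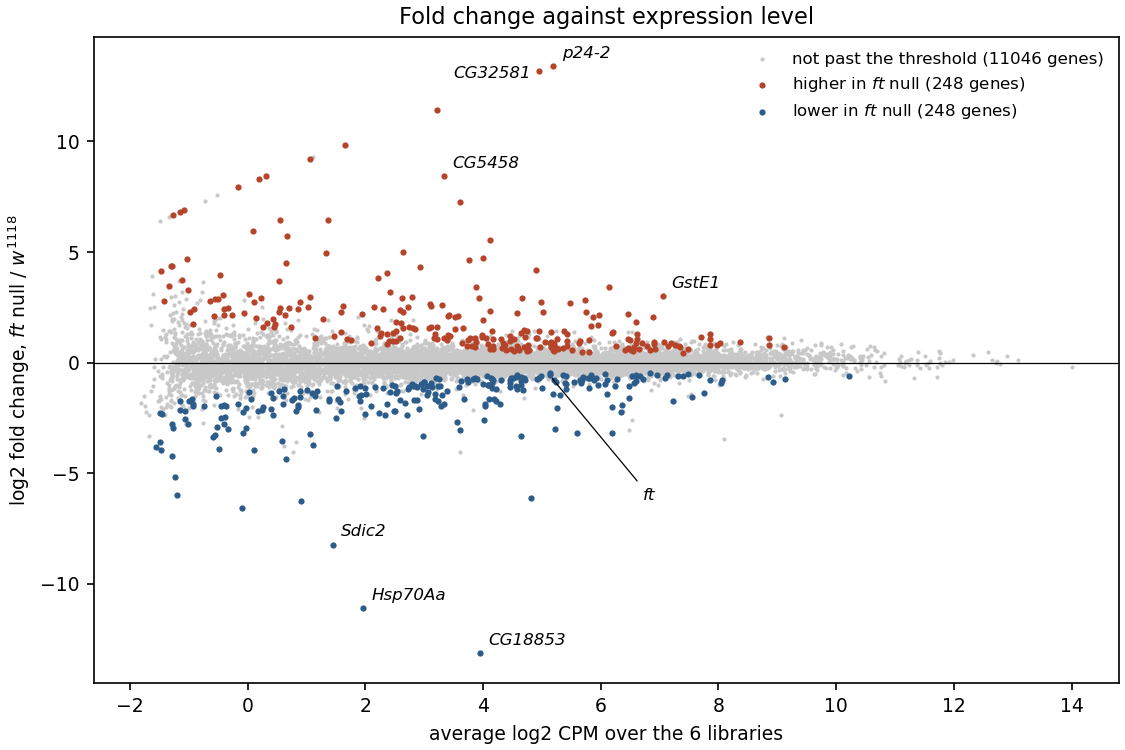
Log2 fold change of each tested gene (vertical axis, *ft* null over *w^1118*) against its average log2 CPM over 6 libraries (horizontal axis), with the 248 higher genes in red, the 248 lower genes in blue and the rest in grey. The genes with the largest fitted changes had no or almost no reads in 1 genotype, and their fitted values there are set by the prior, not by a measured ratio; *ft* sits at -0.57.

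The largest differences were genes detected in 1 genotype and at or near 0 in the other. *p24-2*, a member of the p24 family of vesicle cargo proteins, was at 54.9 ± 12.3 CPM in *ft* null (SD, n = 4) and had 0 reads in *w^1118*, at least 963-fold higher. CG32581 stood at 46.5 ± 3.06 CPM and was at least 815-fold higher, CG42565 at 13.9 ± 1.34 CPM and at least 244-fold higher. The noncoding RNA lncRNA:CR40469 and the pseudogene CR43377 were at least 82.2-fold and 52.9-fold higher. With 2 reads in *w^1118*, CG5458 was 397-fold higher (counting interval 110 to 3280) and CG32984 99-fold higher (27.4 to 817). Both control reads of CG5458 lay in *w^1118* replicate 2. Its fitted log2 fold change was 8.44, but 7.28 without *w^1118* replicate 1 and 11.6 without *w^1118* replicate 2. The serpin gene *Spn42De* rose from 0.104 to 18.3 CPM (log2 fold change 7.27, SE 0.35) and CR43105 from 0.277 to 9.10 CPM (4.98, SE 0.306). The value of *Spn42De* was 8.48 without *w^1118* replicate 1 and 6.77 without *w^1118* replicate 2. *Unc-115b* (5.55, SE 0.932) overlaps *p24-2* on 3R, on the same strand, which leaves their separate values uncertain, and its call was lost without *ft* null replicate 2 or *w^1118* replicate 1 (highest adjusted p of edgeR 0.0591). All its control reads lay in *w^1118* replicate 2, and its fitted value was 4.37 without *w^1118* replicate 1 and 12.3 without *w^1118* replicate 2.

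In the other direction, CG18853 (2R from 7829062 to 7830429) fell from 45.7 ± 5.08 CPM in *w^1118* (SD, n = 2) to 0 reads in the 4 mutant libraries, at least 1450-fold lower. *Hsp70Aa*, 1 of several near-identical copies of the inducible chaperone Hsp70, was at 11.1 ± 6.81 CPM in *w^1118* and at 0 in *ft* null, at least 353-fold lower. The other 4 tested copies, among which its reads are shared by a model, did not pass. The bound for the single copy is therefore uncertain. *Hsp70Ab* was at 225 ± 227 and 1153 ± 9.07 CPM in *ft* null and *w^1118*, and *Hsp70Bbb* at 63.4 ± 81.2 and 691 ± 190 CPM. Both of these copies were named outside the rule. *Sdic2*, from a tandem family of sperm dynein genes, was 372-fold lower (counting interval 103 to 3070), and near-identical sister copies leave its value uncertain. Its fitted log2 fold change of -8.22 moved to -10.6 without *ft* null replicate 2, which held both its mutant reads, and lay at -7.79 without *ft* null replicate 4. CG31683 fell from 82.1 to 1.22 CPM (log2 fold change -6.13, SE 0.514) and the chitinase gene *Cht4* from 5.29 to 0.403 CPM (-3.71, SE 0.285). CG8160 (-3.33, SE 0.434), CG31809 (-3.31, SE 0.382), *phr6-4*, a photolyase gene (-3.23, SE 0.242), and CG42329 (-3.18, SE 0.139) were 9.09-fold to 10.1-fold lower. CG31810, which lies beside CG31809, rose, as described below, and reads exchanged between them were not tested. *Hsp68* completed the 10 largest decreases and is described with the heat shock genes. Adjusted p-values of these 20 genes ran from 2.34e-05 to 0.0423 in edgeR, and CG8160 lost its call without *w^1118* replicate 2 (adjusted p = 0.0683).

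In the pathways in which Fat acts, *ft* was the 1 gene past the threshold. Of 13 Fat-Dachsous pathway genes, *ft* fell and the other 12 did not pass the test, among them *ds*, which encodes the Fat ligand Dachsous, at 71.8 ± 4.83 and 57.0 ± 7.85 CPM in *ft* null and *w^1118* (log2 fold change 0.33, edgeR adjusted p = 0.19). None of 27 Hippo pathway genes, 21 Yorkie targets and 10 core planar polarity genes passed in edgeR, over all genes or adjusted over the list alone, and neither DESeq2 nor limma voom called any. At an unadjusted p under 0.05 in edgeR, 3 Hippo genes and 2 Yorkie targets were lower and 0 were higher, and 0 polarity genes passed. Among Yorkie targets, the caspase inhibitor gene *Diap1* was at 472 ± 35.1 and 472 ± 17.7 CPM (log2 fold change -0.00, SE 0.119), *ex* at 98.9 and 98.8 CPM, *fj* at 38.0 and 37.6 CPM and the cell cycle factor gene *E2f1* at 125 and 121 CPM. The kinase gene *par-1*, with the highest level in the Hippo list, was at 619 and 682 CPM, and *Vang*, a core polarity gene, had a log2 fold change of 0.10. *ds*, *ex* and *fj* were chosen after their values were seen. None of 12 Wingless targets, 14 Notch targets and 18 targets of EGFR, Hedgehog and Dpp passed either in edgeR, with 1, 1 and 2 lower at an unadjusted p under 0.05. DESeq2 called 1 of the last list and limma voom 0 of the 3. Their members with the highest level were *fz2* (log2 fold change 0.26), *ct* (-0.39) and *rdx* (-0.08). The median log2 fold changes of these 7 lists ran from -0.10 to 0.02, and camera called none of them (adjusted p from 0.233 to 0.758). The Hippo list passed without *w^1118* replicate 1 (median -0.15, adjusted p = 0.0254) and the Notch list without *w^1118* replicate 2 (median -0.30, adjusted p = 0.0175), in both cases toward lower levels in *ft* null. With an estimated correlation, which was run only on all 6 libraries, the adjusted p was 0.906 and 0.932.

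Heat shock genes were the list that moved most. Their median log2 fold change was -1.51 over 15 genes, 14 of them below 0, and camera called the list lower (adjusted p = 4.48e-08), as it did in each of the 17 alternative fits (adjusted p up to 1.3e-05), of which limma voom leaves the input of this test unchanged. The median moved to -2.35 without *ft* null replicate 1 and lay at -1.20 without *ft* null replicate 4. With an estimated correlation it was not called (adjusted p = 0.906), and fry gave an unadjusted p of 0.00776 and an adjusted p of 0.256. By edgeR, 4 members fell over all genes and 9 when adjusted over the list alone. *Hsp68* stood at 20.0 ± 20.0 CPM in *ft* null (SD, n = 4) and 179 ± 35.9 CPM in *w^1118* (SD, n = 2). Its log2 fold change was -3.17, but -4.15 without *ft* null replicate 1, where it stood at 49.7 CPM against 7.27 to 14.6 CPM in the other mutants. *Hsp67Bc*, a small heat shock protein gene, fell from 116 ± 10.2 to 56.1 ± 3.86 CPM (log2 fold change -1.05, SE 0.111, edgeR adjusted p = 0.00214) and *DnaJ-1*, an Hsp40 co-chaperone gene chosen after its values were seen, from 87.8 ± 6.08 to 39.2 ± 6.26 CPM, a call lost without *w^1118* replicate 1 (log2 fold change -1.09, edgeR adjusted p = 0.0607). *Hsp83*, a constitutive Hsp90 gene named outside the rule, was at 2236 and 1991 CPM and did not pass. The list varied widely among the mutants. Its median deviation from the mean of the 6 libraries was 0.86 in *ft* null replicate 1 and -0.43, -1.36 and -2.13 in replicates 2, 3 and 4, against 1.57 and 1.52 in the controls. The call of *Hsp68* was lost without *ft* null replicate 2 or 3 or either control (adjusted p of edgeR 0.121, 0.105, 0.149 and 0.148).

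**Figure D2:**
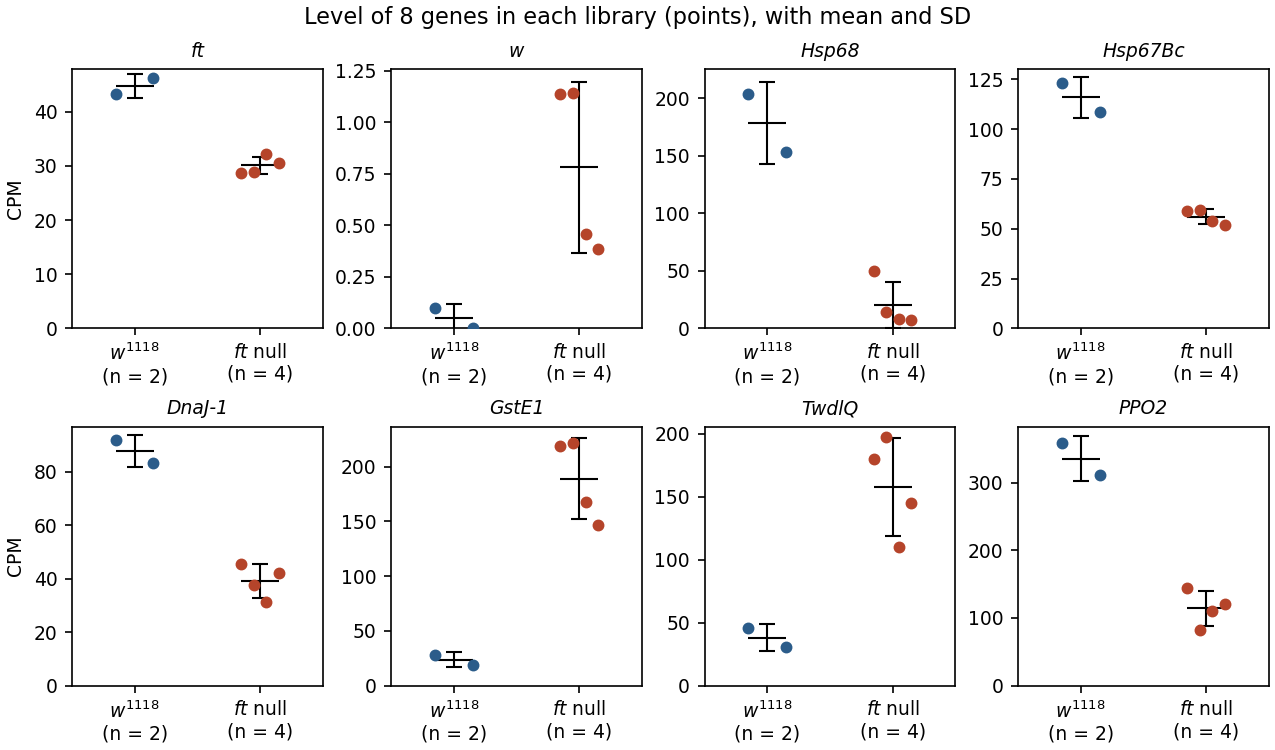
Level in CPM (vertical axis, from 0) of 8 genes in each library, with *w^1118* (n = 2) in blue, *ft* null (n = 4) in red, and bars for the mean and SD. In each of the 8 genes all *ft* null values lie on 1 side of both *w^1118* values, with *w* at 1.14, 1.14, 0.461 and 0.384 CPM in *ft* null and *Hsp68* at 20.0 ± 20.0 CPM.

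Of 108 cuticle protein genes tested, 10 rose, 1 fell and 97 did not pass over all genes, and 17 rose and 2 fell when adjusted over the list alone; the median log2 fold change was 0.25 and camera called the list higher (adjusted p = 0.00474, but adjusted p = 0.906 with an estimated correlation). The Tweedle family, which shapes the larval cuticle, gave 4 of the 10 that rose, a count that was not tested against its share of the list. *TwdlQ* rose from 38.1 ± 10.6 to 158 ± 38.7 CPM (log2 fold change 2.05, SE 0.277, edgeR adjusted p = 0.00636), and *TwdlH*, *TwdlU* and *TwdlE* rose by 2.14, 2.62 and 0.63 on the log2 scale. These 3 and *Cpr60D* were chosen after their values were seen. Their calls were lost without *w^1118* replicate 1 for *TwdlH* (adjusted p of edgeR 0.0659) and without either control for *TwdlU* (up to 0.0894). *TwdlE* lost its call without any library other than *ft* null replicate 1 (up to 0.13). *Cpr60D* lost it without *ft* null replicate 2 or 3 or either control (up to 0.106). *Cpr97Eb* rose from 20.6 to 39.2 CPM (0.93, SE 0.122), whereas *Cpr60D* fell from 3.50 to 0.753 CPM. The list's median deviation was -0.22 in *ft* null replicate 1, below both controls (-0.06 and -0.20), and 0.26, 0.04 and 0.28 in the other mutant libraries. The list median fell to 0.16 without *ft* null replicate 2. The list call was lost without *ft* null replicate 4 (median 0.19, adjusted p = 0.0593) and with replicates 1 and 2 only (median 0.15, adjusted p = 0.158), and the calls of *TwdlQ* and *Cpr97Eb* without *w^1118* replicate 2 (1.80 and 0.89, adjusted p of edgeR 0.0745 and 0.0525). None of 30 genes of chitin and apical matrix and 18 of epidermal barrier and wound healing passed in edgeR. At an unadjusted p under 0.05, 6 and 3 were higher and 3 and 1 lower, DESeq2 called 3 and 1, and limma voom 0 of either list. Their medians were 0.24 and 0.07. *verm*, a chitin deacetylase gene, was at 3814 ± 616 and 2619 ± 563 CPM. *cora*, a septate junction gene, had a log2 fold change of 0.11. Without *w^1118* replicate 1 *cora* moved to -0.22 and *verm* lay at 0.34. Without *w^1118* replicate 2 they lay at 0.53 and 0.785. Without *w^1118* replicate 2 camera called both lists higher (medians 0.35 and 0.18, adjusted p = 0.0175 and 0.0333). Over all 6 libraries the adjusted p with an estimated correlation was 0.906 for both.

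Genes of translation and mitochondrial respiration stood slightly higher in *ft* null as lists, with few single genes. Camera called the cytosolic ribosomal proteins (median 0.32, 83 of 84 genes above 0, adjusted p = 8.77e-09), nuclear-encoded oxidative phosphorylation (median 0.20, 63 of 67, adjusted p = 3.88e-05), mitochondrial ribosomal proteins (median 0.16, 67 of 73, adjusted p = 0.000167) and cell cycle and DNA replication (median 0.30, 28 of 32, adjusted p = 0.0435). With an estimated correlation the adjusted p was 0.906 for each of these 4. By edgeR the genes that rose were *RpS5b* (log2 fold change 1.41, SE 0.261), *RpS15Ab* (0.77, SE 0.157) and *ND-13B*, a complex I subunit gene (0.97, SE 0.139). *RpS5b* and *RpS15Ab* are close paralogs of other ribosomal protein genes, which makes their values uncertain. The call of *RpS5b* was lost without *ft* null replicate 2 or either control (adjusted p of edgeR up to 0.163). That of *RpS15Ab* was lost without *w^1118* replicate 2 or *ft* null replicate 2, 3 or 4 (up to 0.11), and that of *ND-13B* without either control (up to 0.0725). None of the cell cycle and mitochondrial ribosomal protein genes passed in edgeR, with 3 and 8 higher and 0 and 1 lower at an unadjusted p under 0.05. DESeq2 called 1 and 2, and limma voom 0 of either list. *mRpL28* was at 152 ± 9.56 and 146 ± 11.5 CPM. *w^1118* replicate 2 stood apart in these lists, with the ribosomal proteins at -0.54 against -0.03 to 0.28 in the other 5 libraries, and in the mitochondrially encoded genes at -1.35 against 0.18 to 0.43. Without it the ribosomal proteins were no longer called (median 0.06, adjusted p = 0.407), and the medians of oxidative phosphorylation, mitochondrial ribosomal proteins and cell cycle turned to -0.02, -0.05 and -0.01. Without *w^1118* replicate 1 these 4 medians rose to 0.66, 0.45, 0.49 and 0.52. The cell cycle list also lost its call without *ft* null replicate 1 (median 0.07, adjusted p = 0.332) and with DESeq2 (adjusted p = 0.122). Of 13 mitochondrially encoded genes 8 were tested, and *mt:CoIII* rose from 4.56 ± 2.42 to 23.6 ± 5.81 CPM (log2 fold change 2.35, SE 0.359). It held 193 and 62 reads in *w^1118* replicates 1 and 2. Its call was lost without *w^1118* replicate 2 (1.92), and its value lay at 3.05 without *w^1118* replicate 1. Camera called that list only without *w^1118* replicate 1 (median 1.82, adjusted p = 0.000242). None of 34 proteasome genes passed in edgeR (median 0.10; *Rpn6* 149 and 148 CPM), with 1 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma voom. Camera called that list without *ft* null replicate 4 (median 0.13, adjusted p = 0.0296), without *w^1118* replicate 1 (median 0.24, adjusted p = 0.0021) or with replicates 1 and 2 only (median 0.18, adjusted p = 0.0275). For both lists the adjusted p with an estimated correlation was 0.906 over all 6 libraries.

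**Figure D3:**
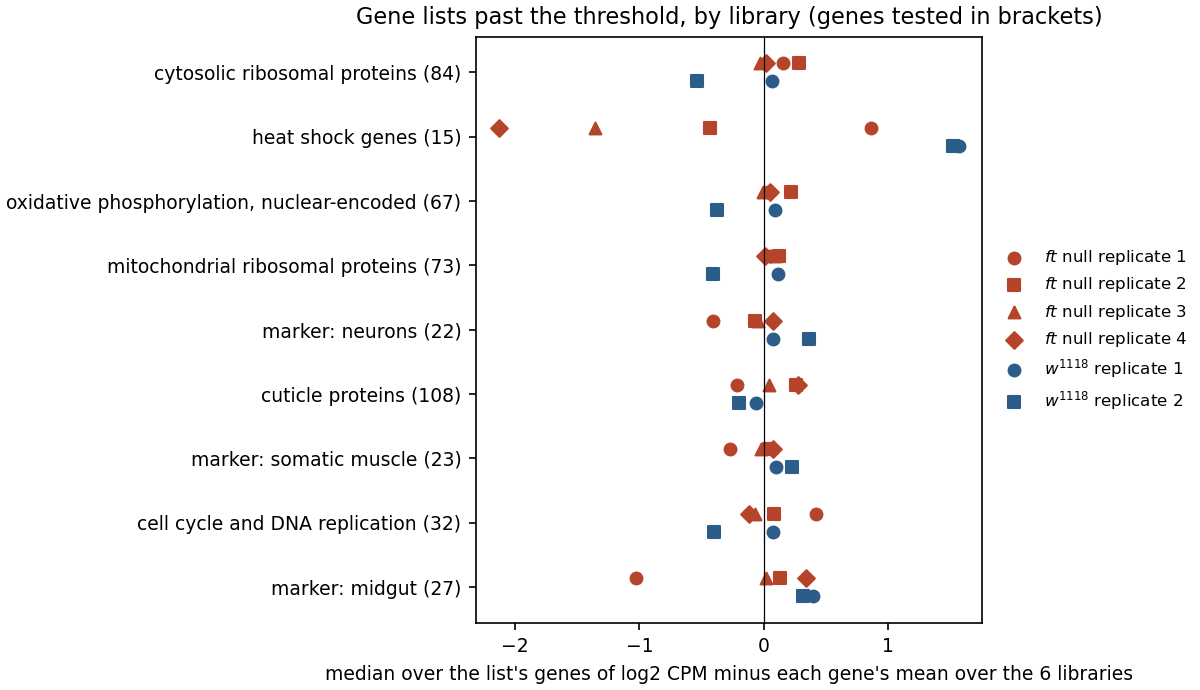
Median over the genes of each list of log2 CPM minus the gene's mean over 6 libraries (horizontal axis, log2 units), for the 9 lists that camera called, with *ft* null replicates in red and *w^1118* replicates in blue. Heat shock genes run from -2.13 to 0.86 in *ft* null against 1.52 and 1.57 in *w^1118*, while the ribosomal and mitochondrial lists differ mainly in *w^1118* replicate 2 and the midgut list in *ft* null replicate 1 at -1.03.

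Markers of 3 cell types stood lower in *ft* null as lists. Developmental stage within the collection window was not tested, so these shifts cannot be assigned to the cell types themselves. Camera called markers of neurons lower in *ft* null (22 genes, median -0.35, adjusted p = 0.00298), of somatic muscle lower (23 genes, median -0.19, adjusted p = 0.0154) and of midgut lower (27 genes, median -0.45, adjusted p = 0.0489). With an estimated correlation the adjusted p was 0.906 for each. By edgeR no neuron or muscle gene passed, with 9 and 5 lower at an unadjusted p under 0.05. DESeq2 called 2 and 5, and limma voom 0 of either list. *brp*, a synapse gene, was at 256 ± 23.8 and 215 ± 87.5 CPM and the muscle actin gene *Act57B* at 15620 and 18080 CPM. The log2 fold change of *brp* was 0.26, above 0 although the neuron list was lower. It moved to -0.11 without *w^1118* replicate 1 and to 0.75 without *w^1118* replicate 2. The midgut protease genes *Jon44E* (log2 fold change -1.91, SE 0.351) and *Jon99Fi* (-2.37, SE 0.513) fell and *Amy-d* rose by 1.20 on the log2 scale, with 8 lower and 2 higher when adjusted over the list alone. *Amy-d* was chosen after its values were seen, and its call was lost without any library other than *ft* null replicate 1 (adjusted p of edgeR up to 0.158). *Jon44E* lost its call without *ft* null replicate 2 or 4 or either control (up to 0.129) and *Jon99Fi* without *ft* null replicate 2 or 3 or either control (up to 0.16). *ft* null replicate 1 was low in midgut (-1.03), neuron (-0.41) and muscle (-0.27) markers. Without it the midgut and muscle calls were lost (medians -0.21 and -0.13, adjusted p = 0.265 and 0.0796), and without *w^1118* replicate 2 the neuron, muscle and midgut calls were lost (medians -0.14, -0.15 and -0.31, adjusted p = 0.556, 0.335 and 0.163). The midgut median moved to -0.69 without *ft* null replicate 2. The mean log2 fold change of that list was -0.05, with 19 genes below and 8 above 0. Its median deviation in *ft* null replicate 4 (0.34) lay above that in *w^1118* replicate 2 (0.314). The midgut call was also lost without *w^1118* replicate 1 (median -0.40, adjusted p = 0.126), under the 3 other scalings (adjusted p = 0.0502 to 0.097) and with DESeq2 (adjusted p = 0.0503).

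Among 20 hemocyte markers, *PPO2*, a prophenoloxidase gene of crystal cells, fell from 335 ± 33.4 to 114 ± 25.7 CPM (log2 fold change -1.55, SE 0.198, edgeR adjusted p = 0.00516) and *Sr-CI*, a scavenger receptor gene, rose from 22.4 ± 4.70 to 42.2 ± 5.28 CPM (0.92, SE 0.175, edgeR adjusted p = 0.0279). Adjusted over the list alone, 2 rose and 1 fell. The list had a median of 0.28 and was not called (camera adjusted p = 0.169). It was called without *w^1118* replicate 2 (median 0.45, adjusted p = 0.00344) and without both that library and *ft* null replicate 1 (median 0.57, adjusted p = 0.0075). With an estimated correlation, run only on all 6 libraries, its adjusted p was 0.906. *btl*, the FGF receptor gene of trachea, rose from 9.27 ± 1.35 to 17.5 ± 1.10 CPM (0.92, SE 0.151) as the 1 of 13 tracheal markers past the threshold, also adjusted over the list alone (list median 0.13, camera adjusted p = 0.169). The remaining marker lists held no call over all genes in edgeR or limma voom. Adjusted over the list alone, 1 fat body gene rose and 1 fell, and 1 gene of Malpighian tubule and hindgut fell. Fat body had a median of -0.11 over 12 genes, glia -0.01 over 14, and visceral muscle and heart 0.12 over 11. Malpighian tubule and hindgut had -0.17 over 12, salivary gland -0.18 over 9, and germline and maternal transcripts 0.09 over 19. Without 1 library the median ran from -0.23 to 0.02 for fat body, -0.155 to 0.12 for glia and -0.22 to 0.28 for germline. The other medians kept their sign. At an unadjusted p under 0.05 in edgeR, 1 fat body gene was higher and 2 lower, 1 glia gene lower, 2 of visceral muscle and heart higher, 1 of Malpighian tubule and hindgut higher and 4 lower, and 1 each of salivary gland and germline lower. DESeq2 called 2 genes of fat body, 1 of visceral muscle and heart, and 1 of Malpighian tubule and hindgut. In the same order, the members with the highest level were *apolpp* (log2 fold change 0.14), *Glt* (0.22), *Fas3* (0.43), *tsh* (-0.36), *Papss* (0.20) and *tud* (0.17). *Glt* moved to -0.12 without *w^1118* replicate 1 and to 0.68 without *w^1118* replicate 2. Camera called Malpighian tubule and hindgut lower without *w^1118* replicate 1 (median -0.36, adjusted p = 0.0254) and salivary gland lower without *ft* null replicate 1 (median -0.33, adjusted p = 0.0342); with an estimated correlation over all 6 libraries the adjusted p was 0.906 for both. *PPO2* lost its call without *w^1118* replicate 1 (edgeR adjusted p = 0.06), *btl* without that library or *ft* null replicate 3 (adjusted p up to 0.0789), and *Sr-CI* without any library other than *ft* null replicate 1 (adjusted p up to 0.127).

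Detoxification genes changed in both directions. Of 26 tested, 3 rose and 2 fell over all genes, and 4 rose and 3 fell adjusted over the list alone (median -0.09, camera adjusted p = 0.609). *GstE1*, a glutathione transferase gene, rose from 23.6 ± 6.89 to 189 ± 37.2 CPM (7.99-fold, edgeR adjusted p = 0.000948), and the glucuronosyltransferase gene *Ugt35b* fell from 3.99 to 0.202 CPM (-4.34, SE 0.466, edgeR adjusted p = 0.00229). The cytochrome P450 genes *Cyp4e2* and *Cyp6a20* rose by 1.12 and 1.91 on the log2 scale, and *Cyp6g1* fell by 1.95. These 3 were chosen after their values were seen, and *Cyp6a20* lost its call without *ft* null replicate 2 or 3 or either control (adjusted p of edgeR up to 0.168). Of 25 ecdysone pathway genes, *Eip93F*, a steroid-induced transcription factor gene, fell from 2.77 to 0.749 CPM (-1.89, SE 0.283; list median 0.00, camera adjusted p = 0.758), a call lost without either *w^1118* library (edgeR adjusted p up to 0.0819). Of 11 antimicrobial and immune genes, *Drsl2* rose from 0.466 to 1.45 CPM (1.62, SE 0.318; list median 0.02, camera adjusted p = 0.756), a call lost without any library other than *ft* null replicate 1 (edgeR adjusted p up to 0.155). Adjusted over the list alone, the same 1 ecdysone gene fell and 1 immune gene rose. None of 18 genes of JNK, apoptosis and stress passed over all genes in edgeR (median 0.00). Nor did any of 4 genes of sex determination and dosage compensation (median 0.02). *Hsc70-3* was at 1193 ± 104 and 952 ± 434 CPM, and *lncRNA:roX1* at 709 and 866 CPM. The log2 fold change of *Hsc70-3* was 0.33, but -0.08 without *w^1118* replicate 1 and 0.89 without *w^1118* replicate 2. Adjusted over the list alone, 1 gene of the first list fell and 1 of the second rose. At an unadjusted p under 0.05, 1 of the first was higher and 1 lower and 1 of the second higher, DESeq2 called 1 and 0, and limma voom 0 of either. For the Fat-Dachsous, Yorkie, ecdysone and JNK lists the median lay at or above 0 while camera's direction was down, and for fat body the mean was 0.01 while the median was -0.11.

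The genotypes carry different second chromosomes, so called genes were counted by chromosome arm. On 2R, 143 of 2332 tested genes were called (6.13%), against 3.87% elsewhere (odds ratio 1.62, 95% interval 1.32 to 1.99, Fisher's exact test, adjusted p = 4.11e-05). On 2L, which holds *ft*, 104 of 2034 were called (5.11%; odds ratio 1.24, 0.985 to 1.55, adjusted p = 0.112). These tests treat genes as independent, whereas 113 called genes had a called neighbour against a median of 48 in shuffles, so the intervals and p-values by region are too narrow. Calls were fewer on 3L (67 of 2286, odds ratio 0.616, 0.467 to 0.802) and X (51 of 1833, odds ratio 0.591, 0.431 to 0.794), and 124 of 2856 genes on 3R (odds ratio 1) and 2 of 93 on chromosome 4 were called. Within 2 Mb of *ft*, 21 of 402 genes were called (5.22%; odds ratio 1.23, 0.744 to 1.93, Fisher's exact test, adjusted p = 0.49), and on the rest of 2L 83 of 1632 (5.09%). Of 5 tested genes on Y, 4 were called (odds ratio 88.9, 8.79 to 4260, Fisher's exact test, adjusted p = 7.52e-05). The *Su(Ste)* copies CR42431, CR42430 and CR42425 were lower and CR41509 was higher, at 0.174 to 1.28 CPM. They were chosen after their values were seen, and their calls were lost without *ft* null replicate 2 or 3 or either control, and for all but CR42431 without *ft* null replicate 4 (adjusted p of edgeR up to 0.222).

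**Figure D4:**
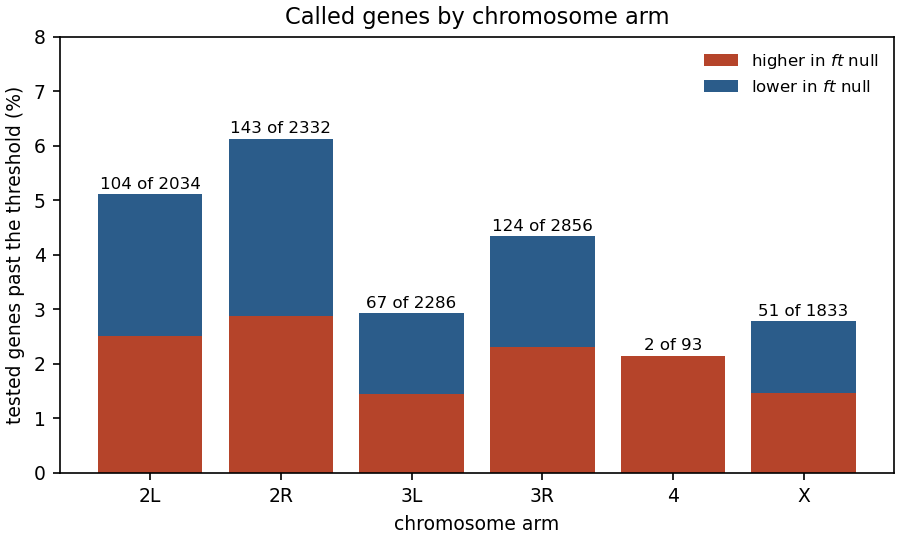
Percentage of tested genes past the threshold on each chromosome arm (vertical axis, from 0), split into genes higher (red) and lower (blue) in *ft* null, with the number called and tested above each bar. The share is 6.13% on 2R and 5.11% on 2L, and 2.93% on 3L and 2.78% on X.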

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

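The tests of the 3 patterns that follow the values in this paragraph were chosen after the results were seen. In all, 97 sets of 4 *ft* null values were examined: 59 named genes, 33 list medians and 5 measures of the libraries. Of these, 3 held a library far from the other 3. The sets share the same 4 libraries and are not independent. Their count is therefore not set against chance and does not show that no library stood apart. *Sdic2* was at 0.0913 CPM in *ft* null replicate 2, from 2 reads, and at 0 in the other 3 libraries. The salivary gland markers had a median deviation of 0.318 in *ft* null replicate 1 against -0.201 to -0.156 in the others, and the Yorkie targets of 0.16 in the same library against -0.0415 to -0.0148.

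Of the called genes, 17 had 0 to 3 reads over 1 genotype and at least 1 CPM in the other, 13 of them detected in *ft* null and 4 in *w^1118*. Variants on the second chromosome that act on their own locus cannot account for all of them, since 7 lie on 3R or X, but variants there that act on other chromosomes were not tested and stay open; 1 of the 17 lies within 2 Mb of *ft*. Of the 17, 13 had no gene within 20 kb called the opposite way by at least 0.5 times their CPM change. That test of reads assigned to a neighbouring copy asks for a call, which a neighbour of higher level could miss. It therefore cannot exclude such reads for genes of low level, such as CG18477 at 1.24 CPM and *vis* at 2.09 CPM in *ft* null. *eca*, the gene beside *p24-2* and named outside the rule, was at 142 and 128 CPM. For the 10 genes on the second chromosome, variants there stay open. Reads from a neighbouring copy stay open for the 4 genes with an opposite call nearby and for those of low level. They also stay open for *Hsp70Aa* and *Sdic2*, because the test cannot see reads shared with copies that move the same way. *Sdic3*, named outside the rule, was called lower like *Sdic2*, and *Hsp70Ab* was lower without passing. Copies farther away were not searched. A strain background other than the *ft* alleles may account for any of the 17. It cannot be told apart from an effect of the genotype, because strain and genotype vary together here. The same holds for all other called genes and for the gene lists.

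Camera with a preset correlation called the ribosomal and mitochondrial protein lists higher in *ft* null while *w^1118* replicate 2 stood apart; with an estimated correlation the adjusted p was 0.906 for each. Without that library the highest of the 3 medians was 0.0613, consistent with a shift carried by 1 control library. Its depth stays open: within *ft* null the 3 libraries within 10% of its depth differed from the 1 at the depth of the other control by -0.0538 or more in the ribosomal protein list, against -0.605 between the controls, but 1 deeper library decides nothing. With 2 control libraries the data do not say which of them is typical of *w^1118*, and a difference by genotype stays open as untested.

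Heat shock genes were lower in *ft* null. A change in the Hsp70 copies alone is argued against by the other 10 heat shock genes, whose median was -1.24 with 9 below 0 and 3 called, and a single library by the highest adjusted p of camera without 1 library, 1.3e-05. These camera calls rest on the preset correlation; the list was not called with an estimated correlation (adjusted p = 0.906) or by fry (adjusted p = 0.256). Handling of the collections stays open: the list median ranged over 2.99 log2 units within *ft* null, the lowest *w^1118* median lay 0.658 above the highest *ft* null one, and the labels name no collection, so that handling and an effect of the genotype, which stays open as untested, cannot be told apart.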

How the results depend on the processing

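Counts of higher and lower genes stayed within 1.5 times of 248 under the 3 other scalings and both filters. They also did so with limma voom, unrounded counts and the 2-fold minimum. No gene called in the main comparison changed sign under any of the 17 alternative fits, which is little evidence. All 496 had their mutant values on 1 side of both controls, so leaving out libraries could not turn a sign. Of the 496, 104 were called in all 17. DESeq2 gave 517 higher and 453 lower, and its simulated false share was also higher. Replicates 1 and 2 alone gave 131 and 117, with fewer samples, and *ft* at -0.636 (adjusted p = 0.115). Leaving out 1 library gave 101 to 425 higher genes, 72 to 381 lower genes, and *ft* at -0.621 to -0.518; the lowest counts came without a *w^1118* library and the highest without *ft* null replicate 1. Without both libraries that stood apart, chosen after seeing the data, 477 genes were higher, *ft* was at -0.509 (adjusted p = 0.0482), and the medians of cell cycle, mitochondrial ribosomal proteins and oxidative phosphorylation turned to -0.146, -0.0496 and -0.0058. Without 1 library these medians ran from -0.0135 to 0.522, -0.0468 to 0.486 and -0.0233 to 0.452, the lowest without *w^1118* replicate 2. Camera with an estimated correlation called 0 lists and fry 0, against 9 with the preset correlation and 6 to 12 when 1 library was left out; 0 lists had an unadjusted p under 0.05 in camera with an estimated correlation and 1 in fry. The odds ratio of 2R ran from 1.28 to 2.16 and kept its call. Whether shared replicate numbers mark a pairing cannot be told from these data. Deviations of same-numbered libraries correlated at 0.153 and -0.0407 across genes, with 2 pairs. With 2 controls their deviations mirror each other, so these are not separate pieces of evidence. The replicate block gave 211 and 244 genes, 279 of them among the 496, and *ft* at -0.635 (adjusted p = 0.0936). With the block *w* passed (4.28, adjusted p = 0.0264), the proteasome list was called (0.191, adjusted p = 0.0303) and the cuticle list was not (0.149, adjusted p = 0.171). *btl*, *Eip93F*, *RpS15Ab* and *Drsl2* lost their calls with the block (adjusted p = 0.0713, 0.0692, 0.0544 and 0.12). Camera read the same log2 CPM in the limma voom alternative, so its p-values there repeat the main ones by construction. Causes of these changes were not tested. Of 986 fits of named genes other than *ft*, 56 lost and 10 gained a call, and *ft* lost its call in 7 of 17 fits. Of 561 fits of lists, 20 lost a call, 6 lost it and changed sign, and 17 gained one. A further 26 gene and 68 list fits changed sign while past the threshold in neither, none above 0.221 in size. These are not counted as reversals. Genes with few reads are limited by depth: the floors given are 3 counts over the libraries of the genotype at 0.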

Other observations

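The genes, gene groups and tests in this part were chosen after the values were seen. None of the called genes changed sign under the other 3 scalings, which genes separated between the genotypes could hardly do. Cytochrome P450 genes were called more often than other genes. Of 77 tested, 15 were called, 8 higher and 7 lower (odds ratio 5.52, 95% interval 2.90 to 9.91, Fisher's exact test, adjusted p = 7.6e-05 over 99 gene families). When single libraries were left out, 8 of the 15 kept their call in all 6 fits, and the others in 1 to 4. The family tests treat genes as independent, whereas called genes lie beside each other, so their intervals and p-values are too narrow. *Cyp309a2* rose from 10.4 ± 2.28 to 74.0 ± 3.17 CPM (log2 fold change 2.83, SE 0.159) while its neighbour *Cyp309a1* fell from 50.3 ± 3.03 to 22.7 ± 4.12 CPM (-1.14, SE 0.173), a call lost without either *w^1118* library (edgeR adjusted p = 0.079 and 0.0698). *Cyp313b1* rose by 2.91 and *Cyp4p2* fell by 3.06 on the log2 scale. Genes of the immune-induced molecule family, short secreted peptides of the Toll response, gave 5 of 7 lower in *ft* null (adjusted p = 0.000139), from 0.698 to 2.59 CPM in *w^1118* to under 0.2 CPM, so that each rests on few reads. All 5 lie on 2R, and when single libraries were left out each kept its call in 2 to 4 of 6 fits. *SPE*, a protease gene upstream of Toll, fell from 35.8 ± 0.0409 to 17.5 ± 0.821 CPM (-1.03, SE 0.109), and *pirk*, a negative regulator of the Imd pathway, from 14.1 ± 1.38 to 5.21 ± 0.400 CPM (-1.44, SE 0.153); both were called in all 17 alternative fits. 

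Other single genes stood out. *Cubn*, a receptor gene for protein uptake in nephrocytes, rose from 35.9 ± 7.60 to 91.2 ± 12.9 CPM, a call lost without *w^1118* replicate 1 (log2 fold change 1.15, edgeR adjusted p = 0.0639). The peroxiredoxin genes *Prx2540-1* and *Prx2540-2* and the adjacent CG12896 rose by 2.92, 2.68 and 4.66 on the log2 scale, all 3 in all 17 alternative fits, although near-identical copies leave their separate values uncertain. The value of CG12896 moved to 6.4 without *w^1118* replicate 1 and to 4.01 without *w^1118* replicate 2. *AGO1*, which encodes the microRNA effector Argonaute-1, fell from 361 ± 34.9 to 142 ± 9.29 CPM, *Pepck2* from 77.0 ± 0.658 to 18.9 ± 4.80 CPM, and *Abl*, a tyrosine kinase gene, rose from 134 ± 22.5 to 280 ± 21.8 CPM. *Tb*, a Tweedle cuticle gene outside the list, rose from 118 ± 36.7 to 289 ± 50.0 CPM, a call lost without *ft* null replicate 2 or *w^1118* replicate 2 (edgeR adjusted p = 0.058 and 0.117). CG31810 rose from 0.873 to 23.6 CPM beside CG31809, which fell from 19.4 to 1.97 CPM, and reads exchanged between these neighbours were not tested.

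Called genes lay beside each other. Of 495 called genes on the chromosome arms, 113 had a called gene as the next tested gene, against a median of 48 and a highest value of 86 in 10000 shuffles of the calls within each arm (permutation p = 0.0001, the smallest they can give). With overlapping genes not counted as neighbours, 84 had one, against a median of 36 and a highest of 68. Of 60 neighbouring pairs, 47 moved in 1 direction. This clustering is consistent with local differences such as haplotypes or shared regulation, which the test does not tell apart.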
